A study of Drosophila melanogaster with 4 samples.

How the data were processed

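Poly(A) RNA from Drosophila melanogaster midguts was sequenced in 4 libraries: untreated and uracil-treated guts, each at 2 h and at 16 h, with 1 library per group. Total RNA had been isolated on Qiagen columns and made into multiplexed Illumina TruSeq libraries. The submitters' processing notes name cutadapt 1.0, TopHat2 2.0.5, Bowtie, HTSeq and edgeR, without the role or settings of each. The genome build, the annotation and the strand setting are not given in the sources used here.

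The deposited table holds 1 signal per gene and library, which the authors call normalized counts. Each value was a whole multiple of 1 step per library (100.0% of values within a tolerance of 0.01 reads), so the signal was read as HTSeq-type gene counts divided by an effective library size, as edgeR does for CPM, counts scaled to a common total, with a normalization factor. The columns summed to 1077970 for untreated 2 h, 968956 for untreated 16 h, 1062205 for uracil 2 h and 980562 for uracil 16 h. Division by the step gave back the reads assigned to genes, 8500378, 16588143, 8990316 and 8841796 in the same order. A single read was worth 0.127, 0.0584, 0.118 and 0.111 normalized counts, and the floor used for a count of 0 was 3 reads, or 0.38, 0.175, 0.354 and 0.333 normalized counts. Fold ratios of named genes are ratios of the normalized counts with exact (Clopper-Pearson) 95% intervals from the reads. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules and no library was repeated.

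Of 13646 lines of the table, 118 shared 57 gene IDs and were summed, which left 13585 distinct IDs. A symbol was found for 12888 of them by ID and none was guessed for the other 697, which held 5.96% to 6.62% of the reads. Coordinates were looked up by ID in Ensembl release 115 (BDGP6.54) and need not be those of the build the reads were aligned to. A set of 84 IDs shared all 4 read counts with another ID (42 groups, among IDs with at least 40 reads), several of them symbols that differ in case or through an alias. These IDs stayed in the genome-wide counts and tests, but are not named as results and were left out of the gene lists (16 memberships). That exclusion was chosen after list medians with them had been seen. It moved the tubule median at 2 h from -0.61 to -0.79, and the other 23 list medians with such members differed by less than 1 SD of random lists.

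For each comparison the log2 ratio of normalized counts was taken after adding 1.02, the mean over libraries of the value worth 1 CPM of the column total. The 8560 genes with a mean of at least 1 CPM over the 4 libraries entered. With 1 library per group, the comparisons at a single time or in a single treatment have no test, and genes at least 2-fold apart were counted in each direction. An effect of uracil shared by both times, and an effect of time shared by both treatments, were tested with limma 3.58.1 (additive model of time and treatment, empirical Bayes with trend) at a Benjamini-Hochberg FDR of 0.05 over the 8560 genes. This fit has 1 residual degree of freedom, the treatment-by-time interaction, and a prior of 5.33 degrees of freedom. The test therefore asks for an effect larger than the disagreement of the times, with the scatter shared over genes, and does not stand in for biological replicates. Each call rests on 2 libraries against 2, which can be divided in only 3 ways.

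The tests were tried on simulated data with 50 genes changed at each of several folds. All simulated genes had the same coefficient of variation, with no time effect and no treatment-by-time interaction. Real genes differ in scatter and can hold an interaction, which is the only residual of the fit. The numbers found in simulated data therefore need not hold for these libraries. With a biological coefficient of variation of 25%, near the 25.3% that edgeR 4.0.16 estimated here, limma found 7 of the 50 genes changed 2-fold, 47 of those changed 4-fold and all 50 of those changed 16-fold, with 11 false calls. The 2-fold size rule found 44 of 50 genes changed 4-fold in the same simulation, but also put 425 unchanged genes 2-fold apart. With a coefficient of 10% it found 49 and put 3 unchanged genes 2-fold apart. The edgeR estimate comes from the same additive model. It therefore holds any real treatment-by-time interaction and does not measure scatter between replicates.

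The gene lists, the rule for named genes, the tests and most of the other settings tried were fixed before the data were examined. There were 42 lists of pathways, gut enzymes, stress and clock genes, markers of gut cell types and markers of other tissues, with 905 memberships. Of these, 819 matched an ID, and 70 did not and are not analysed here. Duox and the stem cell and enteroblast members esg, Dl and hdc are among those not analysed here. No mitochondrially encoded gene matched, and 1 gene of the male reproductive list, bol, was measured. Each list median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a percentile that describes these libraries and is not a p-value. The lists overlap in places: Uro stands in the purine and tubule lists, Cyp6g1 in the P450 and UGT and tubule lists, ZnT35C in the metal-handling and tubule lists, Tsf1 in the stress-humoral and fat body lists, Adgf-A in the purine and fat body lists, and FASN2 in the lipogenesis and fat body lists. Genes were named if they were among the 8 highest or 8 lowest log2 ratios at either time (mean of at least 5 CPM in the libraries compared), the 8 highest or lowest that moved the same way at both times, the 6 highest or lowest over time in both treatments, or the up to 4 members of a list with the largest ratio at either time. The Hedgehog pathway genes hh and Cad99C were named by their place in the design. Other genes named below were chosen after their values were seen: further genes past the limma or edgeR thresholds, further members of described lists, cad, Cyp6a17, Npc1b and members of lists drawn up afterwards.

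Settings tried as chosen in advance were pseudocounts worth 0.25 and 5 CPM, no filter on low values, a filter of at least 10 CPM, median-of-ratios and TMM rescaling, rescaling to the same total, a 3-fold rule, limma without trend, edgeR quasi-likelihood on the recovered reads, and fits without each library. Chosen after the data had been seen were thinning of all libraries to the smallest read total, leaving out IDs that stood on several lines, leaving out IDs with shared counts, and keeping them in the lists. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.

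Because the strand setting is not known, reads of genes that overlap on opposite strands cannot be assigned with certainty. Among the leading genes this holds for CG18585 (overlapping Myo28B1), CG11911 and CG11912 (both inside Plc21C), Arr2 (Pex7), CG15199, osk and CG6996 (antisense or other noncoding RNAs), CG6296 (RYa-R), Ugt49B1 (CG44245), CG32302 (yellow-g), CG16995 (CG9967), mag (atk) and Lsd-1 (CG10214), and on the same strand for mtrm (Exo70). Reads shared between close paralogs, such as the Jonah proteases, trypsins, alpha-mannosidases, lysozymes and Turandot genes, could not be examined from gene counts.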

Results

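The data describe mRNA levels in midguts of flies that had received uracil or no treatment, at 2 h and at 16 h. Uracil is a nucleobase that some gut bacteria release and that is known to trigger production of reactive oxygen by the gut epithelium. Each of the 4 groups had 1 library. Reads in genes came to 8500378 for untreated 2 h, 16588143 for untreated 16 h, 8990316 for uracil 2 h and 8841796 for uracil 16 h. Between 10215 and 10983 genes had at least 1 read, and the 10 most abundant genes took 5.1% to 7.3% of the reads. No difference between single libraries has a replicate to check it against, so such differences are given as higher or lower values without a test. Quantities in brackets after a gene are normalized counts unless named otherwise, and brackets after a fold hold its 95% counting interval.

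The early comparison, uracil against untreated guts at 2 h, asks which mRNAs differ soon after exposure. CG16826 was at 303 normalized counts with uracil and 1.01 without (298-fold higher, 151 to 692), lcs at 98.9 and 1.52 (65-fold, 37 to 126), and whe at 35.9 and 0.254 (142-fold, 38.9 to 1175, from 2 untreated reads). CG7720 was 14.1-fold higher (12 to 16.6) at 284 against 20.2, and TotM, a stress-induced Turandot gene, was 6.57-fold higher (5.73 to 7.56) at 196 against 29.8. CG33109 (12.6 against 0.127) and CG34212 (11.2 against 0.127) rested on 1 untreated read each, with ratios of 99.7 (17.5 to 3974) and 88.5 (15.5 to 3532). The maternal posterior determinant osk was at 23.3 against 3.8, 6.12-fold higher (4.15 to 9.31). On the lower side stood CG12057 (1.18 with uracil, 211 without), the trypsin zetaTry (0.118 and 18.5, ratio 0.00638, 0.00016 to 0.0361, from 1 read), CG18585 (0.827 and 24.3), and the alpha-mannosidases LManVI (30.8 and 345) and LManIII (7.92 and 61.1). CG11912 (11.6 and 86.6), CG33258 (4.49 and 33.7) and CG11911 (139 and 779) were lower as well. In all, 128 genes were at least 2-fold higher and 129 at least 2-fold lower of 8560, a total of 257. Counting noise alone gave a mean of 3.11. Simulated data put 425 unchanged genes 2-fold apart with a coefficient of variation of 25%, and 3 with 10%. The scatter between replicates is not known here, so the simulations cannot say how much of the total is noise. Among genes with a mean of at least 10 CPM the counts were 41 and 92, a share of 30.8% higher in place of 49.8%.

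Cell cycle mRNAs were among the groups that stood highest at 2 h. Of 29 measured genes of the cell cycle and DNA replication list, 10 were at least 2-fold higher with uracil and 0 lower, with a median log2 ratio of 0.83 (percentile 100 of random lists). CycB, a mitotic cyclin, was at 83.3 against 20.2, CycA at 43.0 against 12.7, CycB3 at 11.7 against 2.79, and the mitotic phosphatase gene stg at 8.15 against 1.65. Among members with a mean of at least 10 CPM the list median was 0.1. The female germline and eggshell list, with 6 of 17 matched members measured, moved with this group. Of the 6, 3 were 2-fold higher and 0 lower, with a median of 0.96 (percentile 100). The 3 were osk, pgc (6.14 against 1.27) and bcd (3.78 against 0.888), none of them an eggshell gene. Visceral muscle markers had a median of 0.76 over 15 genes (percentile 100), with 1 of them 2-fold higher. Heat shock genes had a median of 0.43 over 11 genes (percentile 100), and 2 were 2-fold higher, Hsp26 (65.7 against 16.5) and Hsp27 (38.4 against 13.9).

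Digestive and detoxification genes stood on the lower side at 2 h. Of 16 Jonah proteases, which are gut serine proteases, 4 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.26 (percentile 0.0). Examples were Jon66Ci (41.7 against 180) and Jon65Aii (26.9 against 67.3). Among 23 carbohydrases 4 were 2-fold lower and 1 higher (median -0.23, percentile 0.0), led by LManVI, LManIII and LManV (16.5 against 78.4). Of 58 cytochrome P450 and UGT genes 6 were lower and 1 higher (median -0.16, percentile 0.0), with Cyp4d1 at 0.709 against 6.59. Malpighian tubule markers were lower in the same comparison, 6 of 13 by at least 2-fold and 0 higher, with a median of -0.79 (percentile 0.0). The urate oxidase gene Uro was at 14.2 against 82.6, the transporter gene NaPi-T at 15.6 against 49.0 and Oatp58Dc at 9.45 against 34.2. Hemocyte markers had a median of -0.6 over 9 genes (percentile 0.0; -0.1 among members with a mean of at least 10 CPM), with the clotting gene Hml (6.73 against 17.1) and the receptor gene NimC1 (1.42 against 4.57) 2-fold lower.

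The late comparison, uracil against untreated guts at 16 h, asks which differences are present after prolonged exposure. CG16826 was again far higher with uracil (639 against 3.1, 206-fold, 158 to 276), as were whe (103 against 0.234, 439-fold, 171 to 1615) and CG33109 (47.7 against 0.234, 204-fold, 79.1 to 752). A group of neighbouring genes on chromosome 3R, between 17127126 and 17135283, included CG17475 (142 against 0.0584, a ratio of 2428 from 1 untreated read, 435 to 95986), CG31265 (71.5 against 0.876, 81.6-fold, 49.1 to 147), CG31266 (127 against 2.16, 58.9-fold, 42.4 to 84) and CG31267 (78.4 against 1.46, 53.7-fold, 36.1 to 83.5). CG30047 was 107-fold higher (59.3 to 215) at 68.6 against 0.643. Lower with uracil were the photoreceptor genes ninaE, which encodes the major rhodopsin (0.665 against 22.5), and Arr2 (0.111 against 13, ratio 0.00855, 0.000216 to 0.0481, from 1 read). CG15263 (5.1 against 50.6), CG15199 (34.8 against 181), the transferrin gene Tsf1 (3.77 against 21.6), CG17108 (4.99 against 26.3) and the prophenoloxidase gene PPO2 (1.66 against 10.4) were lower too, as was FBgn0259744 (2.0 against 12.9), for which no symbol was found. In all, 656 genes were at least 2-fold higher and 85 lower, so that 88.5% of the 741 were higher.

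Digestive enzymes were among the groups that stood highest at 16 h, the opposite side from 2 h. Of the Jonah proteases 8 of 16 were at least 2-fold higher with uracil and 0 lower, with a median log2 ratio of 0.82 (percentile 100), among them Jon66Ci (118 against 17.5), Jon65Aii (118 against 30.0) and Jon44E (612 against 193). Carbohydrases had 9 of 23 higher and 0 lower (median 0.63, percentile 100), with LManVI at 2054 against 168, LManV at 1072 against 109 and Amyrel at 32.6 against 3.62. Trypsins had 3 of 11 higher and 0 lower (median 0.29, percentile 97.9), namely zetaTry (6.61-fold, 5.91 to 7.4), iotaTry (146 against 22.7) and lambdaTry (552 against 149). Of the cytochrome P450 and UGT genes 8 of 58 were higher and 1 lower (median 0.37, percentile 100), led by Cyp4d1 (93.6 against 10.8), and mucins and peritrophic matrix genes had a median of 0.26 over 10 genes (percentile 98.4), with Muc68D at 2808 against 881. Malpighian tubule markers moved with all of these groups: 8 of 13 were 2-fold higher and 0 lower, with a median of 1.23 (percentile 100), including Uro (210 against 67.2), NaPi-T (224 against 56.4) and Oatp58Dc (87.2 against 34.0). Visceral muscle markers were higher as well, 9 of 15 by at least 2-fold (median 1.03, percentile 100), with Mlc2 at 379 against 139 and bt at 382 against 158. Among genes with a mean of at least 10 CPM the Jonah median was 0.47 and the carbohydrase median 0.38.

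Several metabolic, stress and marker groups stood lower at 16 h. The 15 tricarboxylic acid cycle genes had a median log2 ratio of -0.45 (percentile 0.0) with Idh3a 2-fold lower (253 against 513), and Ogdh was at 706 against 1093. Heat shock genes, higher at 2 h, had a median of -0.34 at 16 h (percentile 0.9), with Hsp23 (1.33 against 8.59) and Hsp22 (4.99 against 22) lower and Hsp27 higher (11.1 against 4.61). Neuron markers had a median of -0.36 over 8 genes (percentile 0.2), with 1 of the 8 above 0. This list includes the photoreceptor gene ninaE, its only member at least 2-fold lower. Hemocyte markers had a median of -0.68 over 9 genes (percentile 0.0), in which PPO2, Hml (2.66 against 9.75) and NimC1 (0.887 against 3.45) were lower and srp (64.8 against 31.5) was higher. The hemocyte median was 0.36 among members with a mean of at least 10 CPM, so its sign rests on members of low abundance. Of the clock genes, per was at 16.3 against 48.4 and then, at 2 h, 46.2 against 26, and tim at 597 against 1246 and 649 against 485. The 10 clock genes went both ways, with medians of -0.1 at 16 h (percentile 52.8) and -0.04 at 2 h (percentile 31.1). At 16 h 2 of them, per and tim, were 2-fold lower and 0 higher. A median over members that move opposite ways cannot show whether the groups differed in time of day. Such a difference was not tested and stays open.

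**Figure D1:**
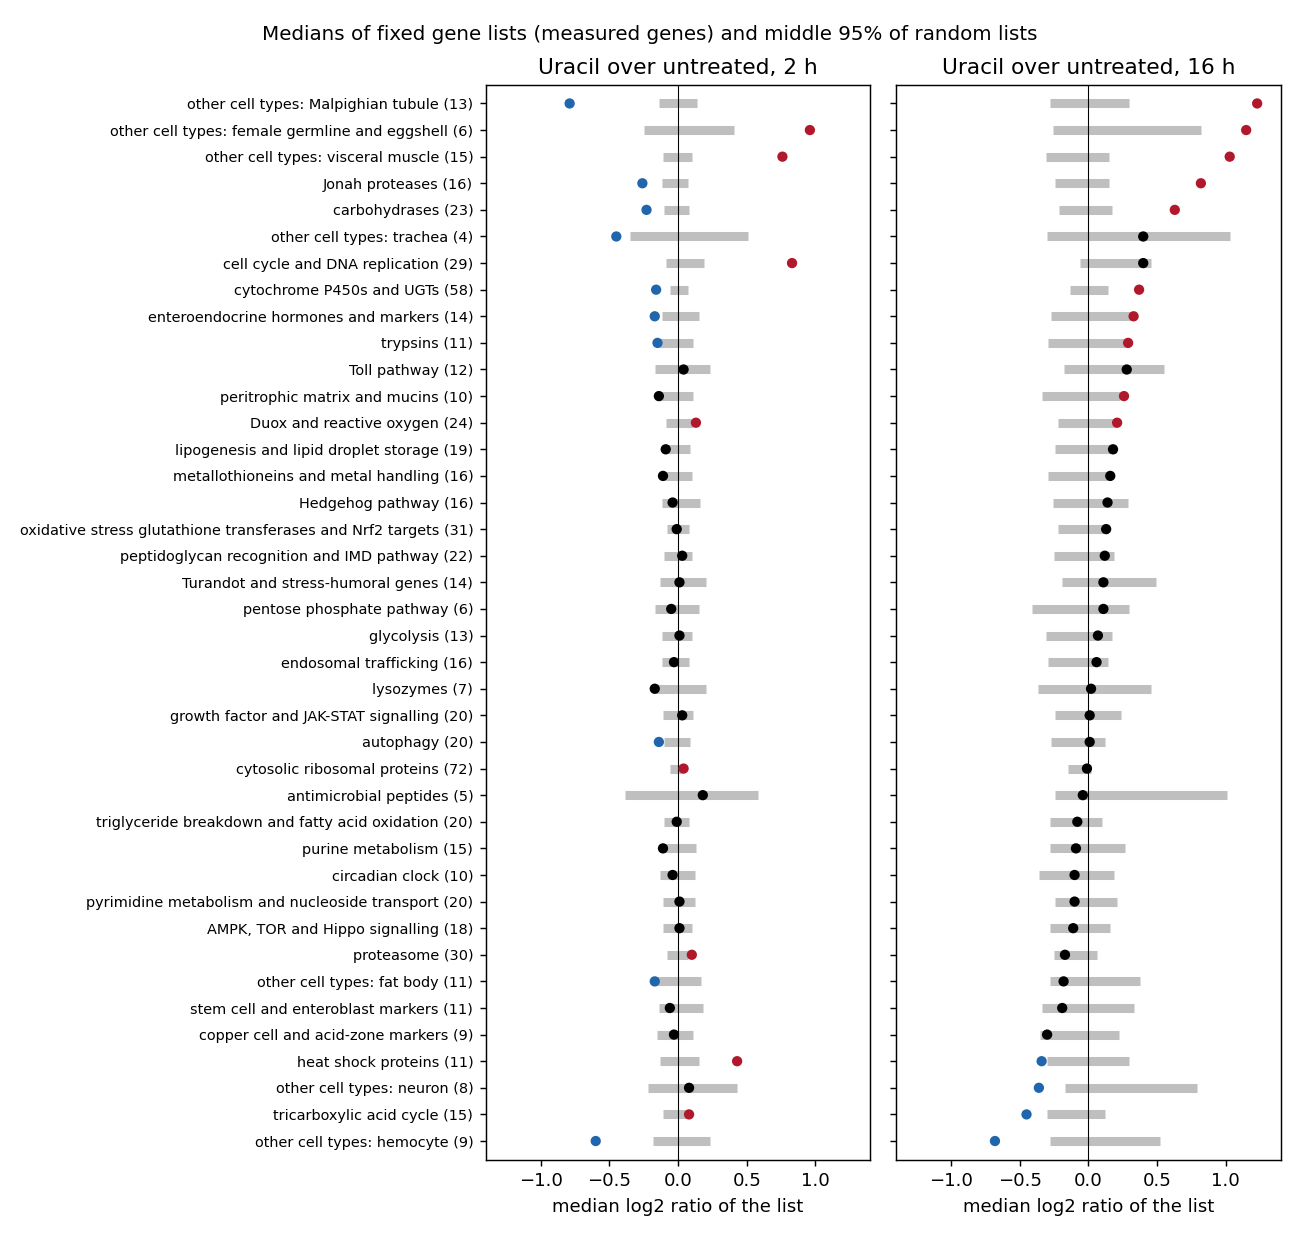
Median log2 ratio of uracil against untreated guts for the gene lists fixed in advance, at 2 h and at 16 h (1 library per group). Malpighian tubule markers lay at -0.79 at 2 h and 1.23 at 16 h, and Jonah proteases at -0.26 and 0.82, while visceral muscle markers were above 0 at both times (0.76 and 1.03).

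Pathways tied to the known gut response to uracil moved little. In the Duox and reactive oxygen list the median log2 ratio was 0.13 at 2 h (percentile 99.0) and 0.21 at 16 h (percentile 97.6) over 24 genes, and mol, which encodes the maturation factor of the oxidase Duox, was 2.33-fold higher at 2 h (1.32 to 4.28) and 3.67-fold higher at 16 h (2.32 to 5.91), at 5.32 against 2.28 and 6.43 against 1.75. Plc21C, a phospholipase C gene, was at 62.7 against 30.3 at 16 h, and CG11911 and CG11912, which lie inside it on the other strand, were higher in the same library. Hedgehog pathway genes had medians of -0.04 at 2 h (percentile 20.9) and 0.14 at 16 h (percentile 86.8) over 16 genes, with ci at 11.3 against 4.73 at 16 h, hh at 26.8 against 34.6 at 2 h and 26.5 against 18.7 at 16 h, and the cadherin gene Cad99C at 3.22 against 1.11 at 16 h and at no more than 2 reads in either library at 2 h. Endosomal trafficking genes lay at -0.03 (percentile 32.6) and 0.06 (percentile 90.6), and autophagy genes at -0.14 (percentile 0.2) and 0.01 (percentile 84.8), with 0 members of either list 2-fold apart. Pyrimidine metabolism and nucleoside transport lay at 0.01 (percentile 50.2) and -0.1 (percentile 26), yet 3 of its 20 genes were 2-fold higher at 16 h: the nucleoside transporter gene Ent3 (33.7 against 6.89) and the pyrimidine breakdown genes pyd3 (43.9 against 16.9) and CRMP (20.7 against 8.18).

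Immune lists stayed within the range of random lists. Antimicrobial peptide genes had medians of 0.18 at 2 h (percentile 68.5) and -0.04 at 16 h (percentile 9.1) over 5 genes, with AttD lower at 2 h (1.89 against 5.33) and Drsl2 lower at 16 h (0.444 against 2.1). Peptidoglycan recognition and IMD pathway genes had medians of 0.03 (percentile 70.9) and 0.12 (percentile 92.2) over 22 genes. The 4 that were 2-fold higher at 16 h were the amidase genes PGRP-SC1b (130 against 18.6), PGRP-SC1a (15.9 against 1.75) and PGRP-SC2 (376 against 172) and the IMD inhibitor gene pirk (189 against 77.5), of which PGRP-SC1b and PGRP-SC1a were 2-fold lower at 2 h (33.0 against 75.7, and 5.2 against 12.4). Toll pathway genes lay at 0.04 (percentile 57.4) and 0.28 (percentile 75.1; -0.13 among members with a mean of at least 10 CPM), with spz at 5.67 against 1.39 at 2 h. Growth factor and JAK-STAT genes lay at 0.03 (percentile 68.1) and 0.01 (percentile 63.9), with the cytokine gene upd3 at 1.44 against 4.67 at 16 h, and stem cell and enteroblast markers at -0.06 (percentile 14.9) and -0.19 (percentile 16.2).

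The remaining gut lists were mixed. Enteroendocrine genes had medians of -0.17 (percentile 0.7) and 0.33 (percentile 98.0; 0.12 among members with a mean of at least 10 CPM) over 14 genes, with the peptide hormone genes Dh31 (19.6 against 5.43) and CCHa1 (17.9 against 6.13) higher at 16 h, and tubule markers moved with this list. Metal-handling genes lay at -0.11 (percentile 3.1) and 0.16 (percentile 97.4), with the zinc transporter gene Zip89B at 180 against 27.0 and the metallothionein gene MtnA at 555 against 194 at 16 h. Copper cell markers lay at -0.03 (percentile 39.1) and -0.3 (percentile 5.8), and CAH1 was lower at 16 h (23.0 against 49.0). Lysozymes lay at -0.17 (percentile 3.9) and 0.02 (percentile 54.9), and the Turandot and stress-humoral list at 0.01 (percentile 40.3) and 0.11 (percentile 47.6; -0.25 among members with a mean of at least 10 CPM). Oxidative stress and glutathione transferase genes lay at -0.01 (percentile 37.8) and 0.13 (percentile 97.2), with GstE5 at 110 against 38.9 and GstE10 at 21.6 against 8.53 at 16 h.

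Apart from the tricarboxylic acid cycle, lists of core metabolism and housekeeping moved by 0.2 or less in median at both times. Lipogenesis lay at -0.09 (percentile 4.9) and 0.18 (percentile 96.5), with the elongase gene eloF at 8.76 against 1.23 at 16 h. Triglyceride breakdown lay at -0.01 (percentile 48.4) and -0.08 (percentile 58.0), with the perilipin gene Lsd-1 at 34.0 against 8.94 and the lipase gene mag at 1348 against 667 at 16 h. Glycolysis lay at 0.01 (percentile 62.5) and 0.07 (percentile 90.1), the pentose phosphate pathway at -0.05 (percentile 27.9) and 0.11 (percentile 86.8), purine metabolism at -0.11 (percentile 4.5) and -0.09 (percentile 34.5), and AMPK, TOR and Hippo signalling at 0.01 (percentile 58.2) and -0.11 (percentile 41.1). Cytosolic ribosomal protein genes lay at 0.04 (percentile 99.5) and -0.01 (percentile 91.4) and proteasome genes at 0.1 (percentile 99.8) and -0.17 (percentile 20.4). Fat body markers lay at -0.17 (percentile 1.9) and -0.18 (percentile 10.7), although the larval serum protein gene Lsp1gamma was at 31.8 against 4.44 at 16 h, and tracheal markers at -0.45 (percentile 1.1) and 0.4 (percentile 65.4) over 4 genes. The male reproductive gene bol was at 20.1 against 23.3 at 2 h and 26.8 against 50 at 16 h. Of 40 lists with at least 4 measured genes, 18 stood outside the middle 95% of random lists at 2 h and 14 at 16 h, though such draws treat genes that vary together as unrelated.

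A uracil effect shared by both times was tested over all 8560 genes. CG16826 (FBgn0032505, chromosome 2L, 13347773 to 13349020) rose with uracil by 7.25 on the log2 scale (SE 0.215, limma adjusted p = 0.000187), higher in both uracil libraries. The gene lcs (FBgn0028583, chromosome X, 21396727 to 21397316) rose by 4.93 (SE 0.266, limma adjusted p = 0.00399), and was 27.4-fold higher at 16 h (22.6 to 33.6). Its neighbour whe (FBgn0031176, chromosome X, 21402339 to 21402772) rose by 5.61 (SE 0.402, limma adjusted p = 0.0154). These 3 were the only genes past the limma threshold, and all were higher. Dividing the 4 libraries the remaining way, untreated 16 h and uracil 2 h against the other 2, also gave 3 genes (394 at an unadjusted p under 0.05), and 3 divisions are too few to judge chance. At an unadjusted p under 0.05 limma gave 392 genes, where 428 of the 8560 would do so by chance, and edgeR gave 426. The 5 genes past the edgeR threshold were these 3, CG33109 (FBgn0053109, chromosome 3R; edgeR adjusted p = 0.00788, limma adjusted p = 0.0813) and CG34212 (FBgn0085241, chromosome 2R; edgeR adjusted p = 0.014, limma adjusted p = 0.0661), the last at 21.7 against 0.117 at 16 h. Without the filter on low values limma gave 29 genes.

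**Figure D2:**
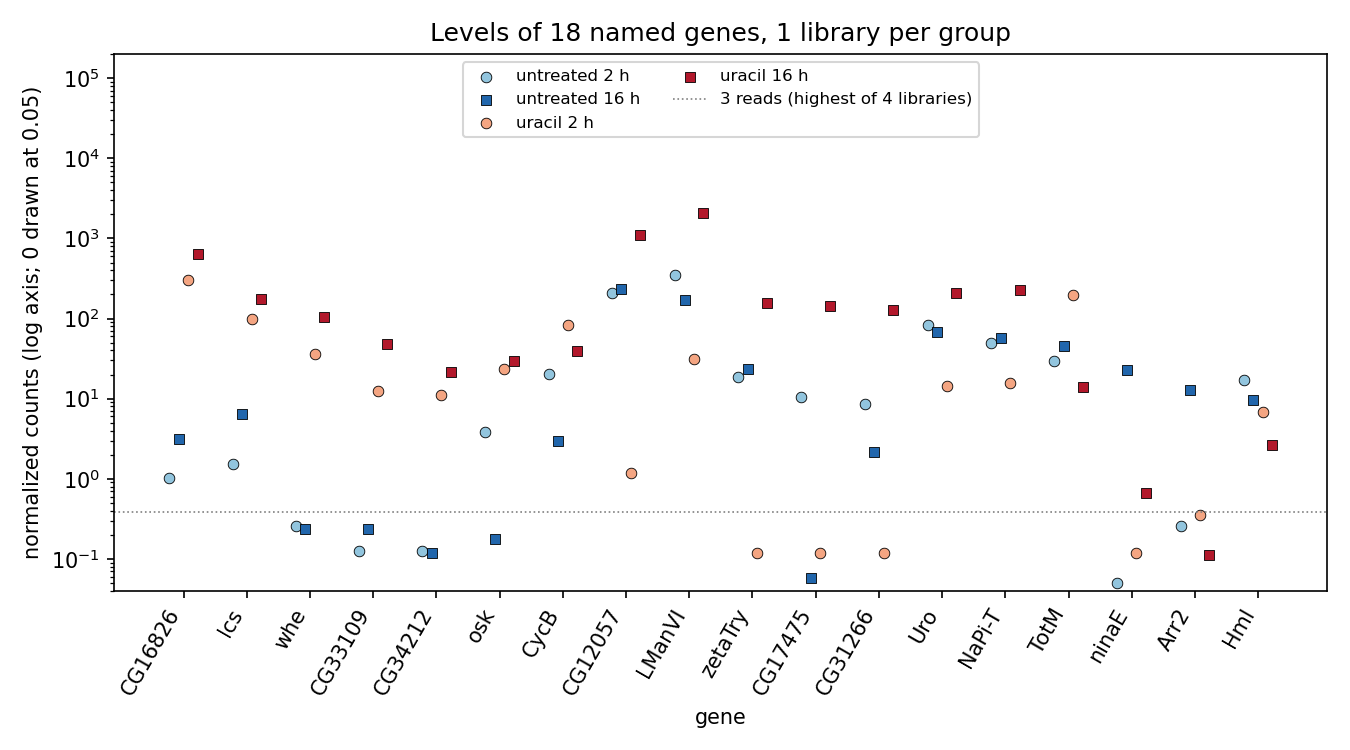
Normalized counts on a log scale in each of the 4 libraries (1 library per group) for 18 genes named in the text. CG16826 lay at 1.01 and 3.1 in the untreated libraries and at 303 and 639 in the uracil libraries, whereas LManVI lay lowest in uracil 2 h (30.8) and highest in uracil 16 h (2054).

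Other genes shared a direction at both times without passing the test. The germline thioredoxin gene dhd was at 114 against 23.7 at 2 h and 36.5 against 1.34 at 16 h, the meiotic regulator gene mtrm at 18.7 against 3.68 and 4.1 against 0.117, and osk at 29.6 against 0.175 at 16 h (a ratio of 169 from 3 untreated reads, 57.2 to 825). CycB was at 38.9 against 2.98 and CycA at 19.9 against 6.78 at 16 h, in a cell cycle list with a median of 0.4 (percentile 94.7) and 5 of 29 genes 2-fold higher. That median was -0.17 among members with a mean of at least 10 CPM. Germline markers moved with these genes at 16 h too (median 1.15, percentile 99.8, 3 of 6 higher), including pgc, which was at 2.99 against 0 and so at least 17.1-fold higher. The sterol uptake gene Npc1b (331 against 92.3 and 277 against 103) had a limma adjusted p of 0.187, and LysX, a lysozyme gene, was at 130 against 38.3 and 39.0 against 13.1. Lower at both times were the acyl-CoA synthetase family gene Acsx3 (4.14 against 12.2 and 14.1 against 37.4), Hml, CG6296 (98.1 against 302 and 93.3 against 185), CG34040 (21.6 against 51.2 and 85.1 against 168), CG4250 (4.49 against 8.75 and 5.21 against 9.93), Ugt49B1 (16.3 against 50.6 and 33.7 against 58.5), the metallothionein gene MtnD (28.4 against 52.5 and 37.0 against 63.3) and FBgn0261362 (5.2 against 12.2 and 2.0 against 11.4), without a symbol.

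Across the 8560 genes the uracil log2 ratios at 2 h and at 16 h had a Pearson correlation of -0.029 and a Spearman correlation of -0.021, as a description across genes that are not independent replicates. Of 165 genes at least 2-fold apart at both times, 64 were higher at both (9.8 expected if the times were unrelated), 4 lower at both (1.3 expected), 95 lower at 2 h and higher at 16 h (9.9 expected) and 2 higher at 2 h and lower at 16 h (1.3 expected). The 2 were TotM and the P450 gene Cyp6a17 (30.6 against 14.3 at 2 h, 5.43 against 17.0 at 16 h). Among the 95 were CG12057, zetaTry, CG18585, LManIII, LManV, LManVI, CG11911, CG11912 and the homeobox gene cad (10 against 27.1 at 2 h, 111 against 31.0 at 16 h). Tubule markers made up 6 of the 95.

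**Figure D3:**
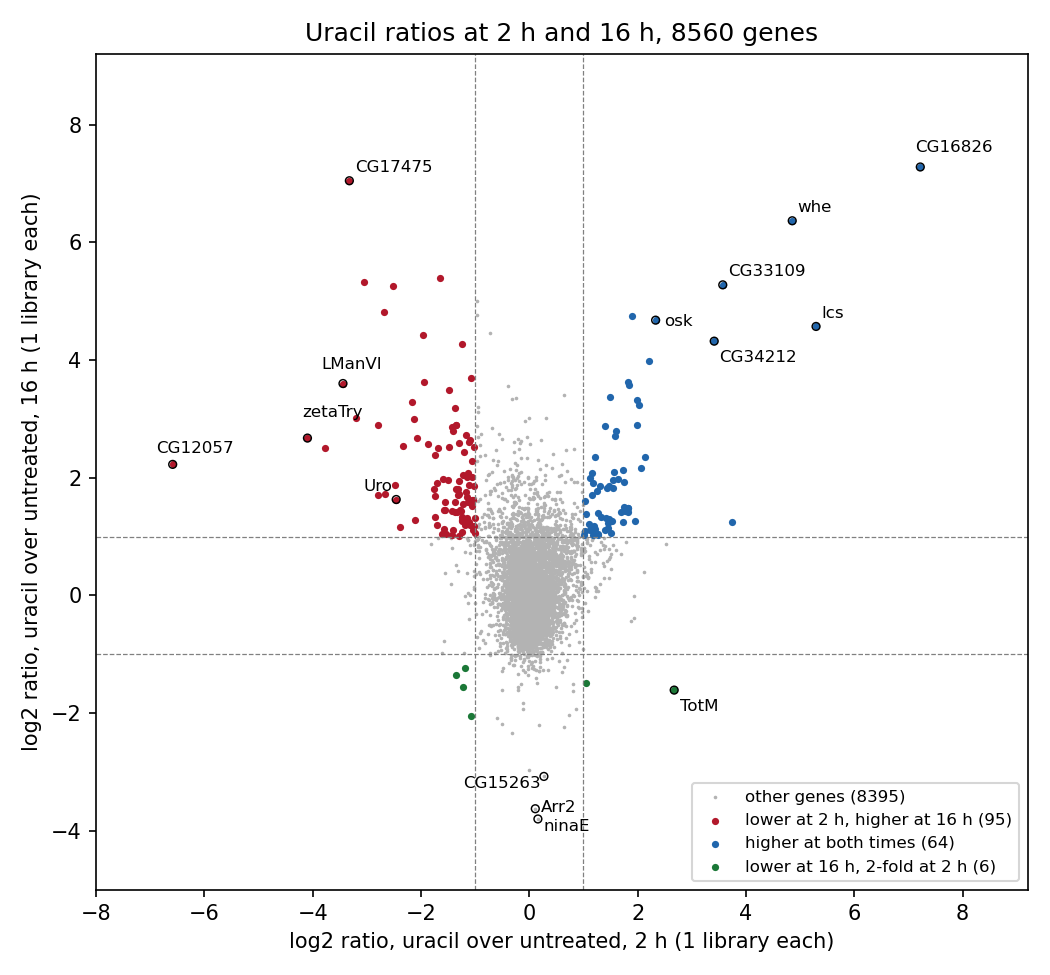
Log2 ratio of uracil against untreated guts at 2 h (horizontal axis) and at 16 h (vertical axis) for 8560 genes, 1 point per gene. Of the genes at least 2-fold apart at both times, 95 were lower at 2 h and higher at 16 h, and 64 were higher at both.

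The time comparisons set the background against which uracil was compared. The cuticular protein gene Cpr49Ae was at 23.5 at 16 h and 0.254 at 2 h in untreated guts and at 67.5 and 0.236 in uracil guts, and rose by 5.02 on the log2 scale (SE 0.41, limma adjusted p = 0.0182). The carotenoid uptake gene ninaD (16.5 and 0.254, then 51.1 and 0.236) rose by 4.58, and Cpr67B (32.8 and 2.28, then 53.5 and 1.77) by 3.82. CG15021 (14 and 0.127, then 26.9 and 0.118), CG5065 (63.4 and 6.85, then 237 and 8.27) and osy (23.8 and 3.68, then 55.6 and 3.31) were higher at 16 h in both treatments. On the lower side, CG7298 (116 and 750, then 82.0 and 879) fell by 3.04 and CG6996 (0.759 and 18.1, then 1.55 and 23.7) fell by 3.35, and CG6933 (4.5 and 34.9, then 3.33 and 33.7), CG32302 (8.35 and 57.3, then 4.77 and 85.1), CG16995 (1.75 and 16.4, then 2.66 and 18.4) and CG12490 (2.75 and 23.7, then 5.32 and 28.7) were lower at 16 h. These 12 genes had limma adjusted p values of 0.0182 to 0.0324, each in the same direction in both treatments. With limma 36 genes passed the threshold, 16 higher and 20 lower at 16 h, and 1368 had an unadjusted p under 0.05. Among them the sugar-digestion genes Mal-A7 and Mal-A2 rose by 1.84 and 1.59 and the tyrosine hydroxylase gene ple by 2.36, while the glutathione transferase genes GstD10, GstD9 and GstD8 fell by 2.4, 2.3 and 2.26 and the protease genes deltaTry, Jon25Bii and Jon25Bi by 2.21, 1.9 and 1.74. edgeR gave 26 genes and limma without the trend 0, and limma gave 18 with all libraries thinned to equal reads.

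In untreated guts 240 genes were at least 2-fold higher and 243 lower at 16 h than at 2 h, and in uracil guts 803 were higher and 248 lower. The time ratios in the 2 treatments had a Pearson correlation across genes of 0.384 and a Spearman correlation of 0.399, and 88.9% of the 270 genes 2-fold apart in both moved the same way. Jonah proteases were lower at 16 h in untreated guts (median log2 ratio -1.2, 12 of 16 genes at least 2-fold lower, percentile 0.0) but not on balance in uracil guts (-0.13, 7 higher and 3 lower, percentile 68.7). Lysozymes were lower in both (-0.99 and -0.88, percentile 0.0 in each), with LysX at 13.1 and 38.3 in untreated guts. Carbohydrases were higher in both (0.24, percentile 99.9, and 0.94, percentile 100), with 3 and 11 of 23 genes 2-fold higher. Tubule markers were at 0.2 in untreated guts (percentile 91.4) and at 2.12 in uracil guts (percentile 100), where 10 of 13 genes were 2-fold higher. Heat shock genes were at 0.18 in untreated guts (percentile 91.6) and at -1.21 in uracil guts (percentile 0.0). With columns rescaled to the same total, which shifted the median of all genes to 0.181, the untreated counts were 379 higher and 185 lower.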

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

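The tests of tissue amounts, sequencing depth, exchanged libraries, dividing cells and genetic background were chosen only after the result was seen. The predictions for ovary mRNAs and for posterior gut regulators were written before those genes were looked at, but both lists were drawn up after the patterns they test. With 1 library per group the differences between 2 h and 16 h had no replicate test. A further limma fit, read after the differences were known, set the difference between the times against the shared uracil effect. That effect was its only residual, with the scatter shared over genes. It called 3 genes of 8560: LManVI (limma adjusted p = 0.0108), CG11912 (limma adjusted p = 0.0323) and CG7025 (limma adjusted p = 0.044). At an unadjusted p under 0.05 it gave 394 genes, where 428 would do so by chance. The other single genes given here did not pass it, the differences between lists were not tested, and all are given because the uracil ratio had opposite signs at the 2 times. Missing the threshold need not mean a smaller difference, since this fit favours 2 ratios of equal size and opposite sign. CG17475, with log2 ratios of -3.32 and 7.05, had a limma adjusted p of 0.192.

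The uracil ratio turned from lower at 2 h to higher at 16 h for 95 genes. Malpighian tubule tissue left on the guts in unequal amounts may account for part of the pattern: the tubule list swung by a median of 1.69 on the log2 scale between the times (percentile 100 of random lists), and 6 of its markers are among the 95, so that source cannot be told apart from a change in the gut. For 18 genes the lower counting bound of the swing exceeded 4.39, the upper bound of the markers, but the genes were picked by their swing, the make-up of the tissue was not measured and the markers themselves ranged from -0.08 (Picot) to 4.09 (Uro), so tubule tissue stays open for them too. Unequal depth was argued against, since 92 of the 95 genes remained after thinning to equal reads; an exchange of the 2 h libraries would turn to opposite signs CG16826, lcs, whe, CG33109, CG34212, the 64 genes higher at both times (9.8 expected) and visceral muscle (15 of 15 genes above 0 at both times), but would give the same sign to the 95 genes (9.9 expected), and no value forbids it, since limma called 3 genes with either labelling and the correlation after the exchange, 0.029, is the reported one with its sign turned. An unequal share of the posterior end of the gut stays open, as does a response to uracil that reverses with time, which was not tested: 4 other posterior and hindgut regulators swung by a median of 0.88 (percentile 98.9), but mainly through 16 h (median 0.9, percentile 99.4) and hardly at 2 h (-0.05, percentile 29.0), and the requirement that each time shift was made strict only after these values were known. These 4 were the measured members of 7 listed. Their log2 ratios at 16 h were 1.54 for abd-A, 1.37 for drm and 0.44 for bowl, but -0.59 for exex, the most abundant.

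Single genes of this pattern had the following differences between the log2 uracil ratios, 16 h minus 2 h. The difference was 8.81 for CG12057, 6.77 for zetaTry, 6.29 for CG18585, 7.04 for LManVI, 4.5 for LManIII, 5.69 for CG11912, 4.36 for CG11911 and 4.38 for CG33258. It was 10.37 for CG17475, 8.39 for CG31266, 7.77 for CG31265 and 7.04 for CG30047. In the other direction stood 2 genes, TotM, with a difference of -4.28, and Cyp6a17. Among the gene lists the difference of the medians was 2.02 for Malpighian tubule markers, 1.08 for Jonah proteases, 0.85 for tracheal markers and -0.77 for heat shock proteins. The tracheal list had 4 genes and lay within the range of random lists at 16 h (percentile 65.4). Further lists also turned from below 0 at 2 h to above 0 at 16 h. Among them were carbohydrases (-0.23 and 0.63), P450 and UGT genes (-0.16 and 0.37) and enteroendocrine genes (-0.17 and 0.33).

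Female germline mRNAs were higher with uracil at both times and cell cycle mRNAs at 2 h, whereas the cell cycle median at 16 h (0.4, percentile 94.7) lay within the range of random lists, and among members with a mean of at least 10 CPM it was 0.1 at 2 h and -0.17 at 16 h. Ovary RNA in the uracil libraries is a candidate source: 29 other ovary and maternal mRNAs had medians of 0.48 at 2 h (9 genes 2-fold higher, 0 lower) and 0.91 at 16 h (13 higher, 0 lower), each at percentile 100 of random lists. Among them BicC was at 33.0 against 8.5 and 16.0 against 0.409, and alphaTub67C at 15.2 against 4.31 and 7.32 against 0.175. Not higher were tud (319 in both 2 h libraries, 293 against 484 at 16 h) and egl (222 against 230, 184 against 253). Among other well expressed members, log2 ratios at 2 h and 16 h were near even for exu (0.07, 0.08) and stwl (-0.18, -0.09). The same held for armi (0.17, -0.14) and fs(1)K10 (-0.26, -0.05). Of comparable mean abundance, BicC and cup (0.89, 0.43) were higher at both times and del (1.0) at 16 h. The list medians therefore rest largely on members of low abundance. Messages that the gut itself expresses need not be higher, so the abundant members do not exclude ovary RNA. More dividing cells in the midgut stay open beside it, since many cell cycle mRNAs are made in both tissues and more divisions need not bring more stem cells. The stem cell and enteroblast list gave no sign of a larger share, with 4 of 11 genes above 0 at 2 h (median -0.06) and 0 of 11 at 16 h (median -0.19, percentile 16.2). Its members esg, Dl and hdc were not analysed here, so the list cannot exclude a larger share. Germline markers were also lower at 16 h than at 2 h in untreated guts (median -0.84, percentile 0.0), so the untreated libraries differed in them too. Of the 17 matched members of that germline and eggshell list 6 were measured. The 3 that were 2-fold higher at 2 h, osk, pgc and bcd, are not eggshell genes.

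CG16826, lcs, whe, CG33109 and CG34212 were far lower in both untreated libraries than in both uracil libraries, with 1 to 4 untreated reads for whe, CG33109 and CG34212 but 53 for CG16826 and 109 for lcs at 16 h. RNA of another tissue in both uracil libraries might bring more such genes, and 0 further genes were at least 8-fold higher at both times. That count cannot decide, since markers of other tissues were higher at both times without reaching 8-fold at both. Visceral muscle had medians of 0.76 and 1.03, with 15 of 15 genes above 0 at both times, and female germline markers 0.96 and 1.15. A tissue marked by few abundant genes cannot be ruled out either. With flies of another genetic background in the uracil groups, such differences could extend to neighbouring genes, and 0 other genes within 100 kb of the 5 were 2-fold apart the same way at both times, where the middle 95% of random sets extended to 2. That count left out the 5 themselves, of which lcs and whe lie 5023 bases apart, a pair within 100 kb that 3% of random sets of 5 genes had, and a variant acting on 1 gene would leave no neighbour, so this explanation stays open. The labels name no second background or batch, but each group is 1 library, so either explanation and a response to uracil cannot be told apart here.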

How the results depend on the processing

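Thinning to equal reads, leaving out IDs on several lines or with shared counts, and keeping shared-count members in the lists were chosen only after the results had been seen. The surplus of higher genes at 16 h (88.5%) lay between 86.0% and 93.1% under each setting tried, and the even split at 2 h held in all but the filter at 10 CPM (30.8% higher) and the pseudocount of 5 CPM (43.0%). The shared uracil effect was called for 2 to 5 genes under each setting that kept a filter on low values. TMM rescaling left all 91 values recomputed with it near those reported, with counts within 1.5 times and list medians within 1 SD of random lists, and median-of-ratios rescaling left all 8 counts so. Beyond the comparison within each time that the additive model makes, no paired analysis was possible because the labels carry no replicate numbers and each group has 1 library. Without 1 library at a time the shared effect is the ratio at the other time, with no test left, and ranged from 4.57 to 5.3 for lcs and from 4.86 to 6.37 for whe. Depth limits the genes with few reads: ratios against 1 to 3 reads span more than 10-fold in their counting intervals.

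The pseudocount of 0.25 CPM gave 204 genes higher at 2 h and 20 genes with a shared time effect. The pseudocount of 5 CPM gave 40 genes higher and 53 lower with uracil at 2 h, 374 and 49 at 16 h, 80 and 133 over time in untreated guts, and 488 and 158 in uracil guts. With it the list medians at 2 h were 0.51 for cell cycle, -0.42 for hemocyte, -0.47 for tubule, 0.49 for germline and -0.23 for trachea, and at 16 h 0.48 for carbohydrases, 0.23 for cell cycle, 0.91 for tubule and 0.53 for germline. A larger pseudocount draws ratios of low values toward 0 by its construction.

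The filter at 10 CPM gave 41 genes higher at 2 h, 355 higher at 16 h, 137 higher and 155 lower over time in untreated guts, 425 higher and 165 lower in uracil guts, and a correlation of -0.128. It has fewer genes by its construction. At 2 h the medians were -0.28 for carbohydrases, -0.04 for growth factors, 0.1 for cell cycle, -0.23 for P450 and UGT genes, 0.13 for Turandot, -0.1 for hemocyte and -0.61 for tubule. At 16 h they were -0.13 for Toll, 0.47 for Jonah, 0.38 for carbohydrases, -0.17 for cell cycle, -0.25 for Turandot, 0.12 for enteroendocrine, 1.02 for tubule and 0.36 for hemocyte, the last with its sign reversed. Toll, cell cycle and Turandot at 16 h and growth factors at 2 h changed sign as well, from medians within the range of random lists. Which members each filter removed was not followed further, and the cause was not tested.

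The 3-fold rule, stricter by its construction, gave 37 genes higher and 36 lower at 2 h, 244 and 18 at 16 h, 45 and 68 over time in untreated guts, and 419 and 56 in uracil guts. Rescaling to the same total gave 379 genes higher over time in untreated guts, with the median of all genes shifted to 0.181. Without the filter on low values limma gave 29 genes for uracil and 329 for time. edgeR gave 5 genes for uracil. For time, limma without the trend gave 0 (1270 at an unadjusted p under 0.05, and 26 past the threshold with edgeR) and 18 on thinned reads; the cause was not tested. With shared-count members kept, the tubule median at 2 h was -0.61.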

Other observations

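The tests of chromosomal clusters and of eye RNA were chosen only after the results had been seen. Cuticular protein genes of the Cpr family, a group picked out after Cpr49Ae and Cpr67B had been seen, were higher at 16 h in part: of 5 measured, 2 were at least 2-fold higher at 16 h in untreated guts, 4 in uracil guts and 2 in both. The 2 in untreated guts and in both were Cpr49Ae and Cpr67B themselves. No other member was 2-fold higher in untreated guts, where Cpr57A was at 0.759 and 0.761 and Cpr78E at 3.1 and 1.78, at 16 h and 2 h. The counts for untreated guts therefore add nothing to the genes that led to the group. Cpr51A was at 3.15 and 1.9 in untreated guts and at 13.6 and 2.13 in uracil guts, at 16 h and 2 h.

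The genes that turned from lower at 2 h to higher at 16 h lay near one another on the chromosomes. Among the 91 with coordinates and with read counts that no other ID shared, 30 pairs had starts within 20 kb, where random draws of as many genes matched on expression gave a median of 3 and reached 7 at the upper end of the middle 95%. The pattern gathers in clusters of neighbouring genes on the chromosomes, as a hypothesis found on these data. Whether the neighbours are related, and whether other sets of gut genes gather as much, was not tested. The largest held CG31269, CG31265, CG17475, CG4053 and CG31266 on chromosome 3R (17127126 to 17133719). Next, with 3 genes each, came LManIII, LManV and LManVI on 2L (8765273 to 8781252) and CG6726, CG17110 and CG6733 on 3R (23091724 to 23099191). CG6726 (3R, 23091724 to 23095184) and CG17110 (23091724 to 23095441) overlap on the same strand and make 1 of the pairs; 28 pairs remained without CG17110. Reads shared between neighbouring paralogs would add such pairs and were not tested.

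The photoreceptor genes ninaE and Arr2 were lower with uracil at 16 h, and were high only in untreated 16 h. Eye RNA in the untreated 16 h library may be the source. The 6 other phototransduction genes had a median log2 ratio of -0.03 at 16 h (percentile 17.5), with Arr1 at 0.222 against 8.76 and the others nearer to even. Their median cannot decide, since members such as norpA (17.9 to 24.9) and rdgB (18.8 to 32.6) were present in all 4 libraries. Arr1, like ninaE and Arr2, was high only in untreated 16 h, with 0 in both 2 h libraries. The test left the source open.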
